A study of Mus musculus with 5 samples.

How the data were processed

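RNA-seq gene counts were analysed from MutuDC cells, an established mouse dendritic cell line of the cDC1 kind, treated with Fanchinoline (spelled as in the labels). The labels give 5 samples: a vehicle control, taken as 0 h, and cells after 2, 6, 12 and 24 h with the compound. The design text of the series instead names untreated cells as the control, so whether the 0 h cells received the solvent is unsettled, and ratios to vehicle may include an effect of the solvent. Per the labels' protocols, total RNA was extracted with TRIzol, poly-A RNA was purified on oligo-dT beads, and libraries were made with a TruSeq RNA kit that does not mark strand. The dose is not given in the sources used here.

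The authors deposited a table of raw counts per gene, with 53700 genes named by Ensembl identifier and symbol and 1 count column per time point. The submitters' processing notes name Trim Galore, HISAT2 and the mouse build GRCm38, without versions. The program that counted reads and its annotation are not given in the sources used here, nor is whether counting used strand or how reads matching several genes were treated. The design text of the series speaks of triplicates, while the deposited count table holds 1 library per time point; whether these pool replicates is not stated. No replicate spread between conditions could therefore be measured, and no p-value is given for any comparison of 2 time points. The vehicle library is the only one without the compound, so exposure to Fanchinoline and hours in culture change together.

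Total counts per library lay between 33568526 and 42854511. At 10 CPM (counts scaled to library size) a gene had 328 to 427 counts. Intervals are 95% exact (Clopper-Pearson) intervals of the ratio of 2 scaled counts; they take 1 count as 1 read and cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Whether the counts are reads or were derived from coverage is not given in the sources used here, and if derived, the intervals would not hold as stated. A count of 0 allows up to 3 counts, or 0.070 to 0.092 CPM.

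Counts were scaled with edgeR's TMM factors (0.977 to 1.05) and turned into log2 CPM with a prior count of 2 (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Genes with at least 10 CPM in at least 1 of the 5 libraries were compared (8846 genes). A gene was called higher or lower when its log2 ratio was at least 1 in size and its interval excluded a ratio of 1. This rule of size compares libraries, not conditions. The same rule was applied between consecutive time points. A trend over all 5 libraries was tested with edgeR's quasi-likelihood test of a slope on log2(hours + 1). It used filterByExpr, Benjamini-Hochberg adjustment over 13877 genes and an adjusted p threshold of 0.05. Its spread is the lack of fit around the line, with 3 residual degrees of freedom per gene. The test also borrows spread across genes, so its p-values do not rest on these 3 alone.

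Gene lists (41) were written from textbook knowledge: lipid, lysosome, stress, metabolism, ribosome, cell cycle, cell death, inflammation, antigen presentation and dendritic cell genes, markers of other cell types, signs of RNA quality and housekeeping genes. For each list with at least 3 measured members (34 lists), the median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 strata. The percentile describes these libraries and is not a test across samples. Lists matched on transcript length as well were added after the data were seen. Of 34 lists of genes drawn at random, 0.85 would lie above percentile 97.5 in a comparison, and as many below 2.5. Genes of 1 real list may vary together, and some lists share members. More real lists may therefore lie outside these limits without an effect of the compound. At 2, 6, 12 and 24 h against vehicle 3, 6, 5 and 6 lists lay above and 7, 12, 12 and 10 below. Where a symbol had several gene entries, lists used the entry with the most counts.

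Named genes were, for each time point against vehicle, the 12 highest and the 12 lowest called genes with at least 10 CPM in the higher library and an ordinary symbol; up to 4 members per list with the largest ratio in size at 24 h; 16 genes fixed by name (among them Sqstm1, Ddit3, Hspa5, Hmox1, Irf8, Xcr1, Cd86, H2-Ab1, H2-K1, Mki67, Cdkn1a, Myc, Isg15 and Tnf); and the 6 highest and 6 lowest slopes among genes past the trend threshold with a mean of at least 10 CPM and an ordinary symbol. The size rule, trend test, lists, named-gene rule and the other settings listed last below were fixed before the data were examined. Results for some genes that this rule takes are not reported here. Other genes are named only as members that make up a count, and were chosen after their values were seen.

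Positions, transcript lengths, GC content and overlaps came from GENCODE's mouse annotation on GRCm38; 99.88% of compared genes were found in it. After ratios against vehicle were seen to rise with transcript length, log2 ratios and their intervals were also computed minus a loess fit (span 0.5) on log2 transcript length and GC content, called length-adjusted here. The comparison of 24 h over 2 h, which leaves out vehicle, and counts without genes whose exons overlap another gene on the same strand were added at the same point. Other settings fixed earlier were DESeq2 size factors (DESeq2 1.42.0), total counts alone, minimums of 1 and 30 CPM, a prior count of 0.5, folds of 1.5 and 4, and for the trend DESeq2's Wald test, other filters, other time scales and each time point left out. Figures were drawn with matplotlib 3.10.9.

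The steps were tested on simulated counts with 200 changed genes. The size rule recovered 98.0% of genes changed 3-fold and 100% of those changed 6-fold between 24 h and vehicle, with 8 false calls among 8794 genes. The trend test recovered 99.0% and 100% at these folds over 24 h, with 3 false calls among 13787 genes. The simulated spread was negative binomial with a dispersion of 0.02. The changed genes were drawn at a mean level above the minimum of 10 CPM used here. These runs also held no transcript length difference of the vehicle library. Recovery may therefore be lower, and false calls more frequent, in the real libraries.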

Results

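Gene expression was measured by poly-A RNA-seq in MutuDC cells, a mouse dendritic cell line, before and during treatment with Fanchinoline. Libraries stood at 0 h (a vehicle control per the labels, untreated cells per the design text), 2, 6, 12 and 24 h, with 1 library per time point and none of the differences below checked by replicates. Total counts were 33568526 in vehicle, 37589066 at 2 h, 42854511 at 6 h, 37999354 at 12 h and 40730837 at 24 h. The series asks which genes and pathways the compound alters over time. Log2 ratios against vehicle are given with 95% exact intervals that cover counting error only, and no vehicle library was taken at the later times.

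The vehicle library stood apart from all 4 treated libraries in the balance of long and short transcripts. The median log2 ratio of the longest quintile of transcripts lay above that of the shortest by 0.57 at 2 h, 0.65 at 6 h, 0.69 at 12 h and 0.75 at 24 h. Between treated libraries the same difference was 0.06 for 6 h over 2 h and 0.16 for 24 h over 2 h. The treated libraries differed more by GC content. The median of the highest GC quintile minus that of the lowest was -0.35 for 24 h over 2 h. Against vehicle this difference was 0.23 at 2 h, 0.16 at 6 h, -0.02 at 12 h and -0.13 at 24 h. Mitochondrially encoded genes took 2.52% of counts in vehicle and 1.44% to 1.75% in the treated libraries. Values adjusted for transcript length and GC content, called length-adjusted, are given beside a part of the results.

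**Figure D1:**
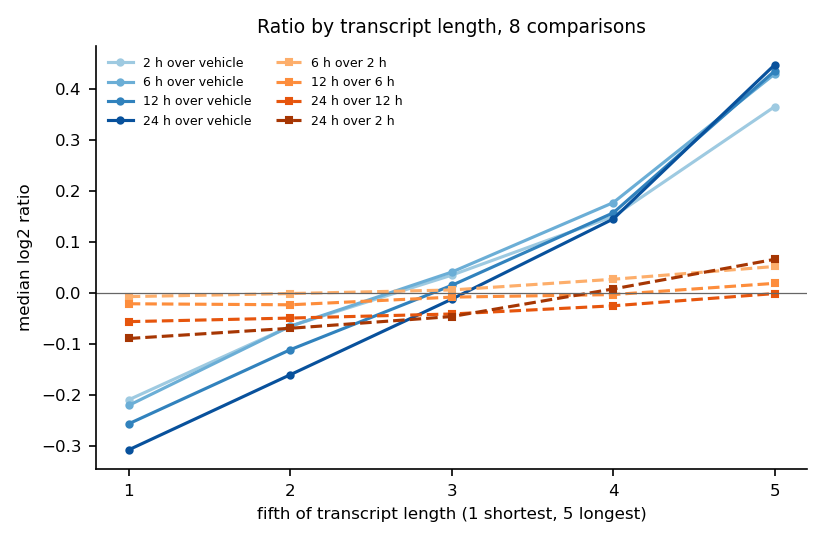
Median log2 ratio of genes (y axis) in quintiles of transcript length, from shortest to longest (x axis), for 4 comparisons with vehicle (circles, solid lines) and 4 between treated libraries (squares, dashed lines), with 1 library per time point. The lines against vehicle climb with length, by 0.57 to 0.75 from the shortest to the longest quintile, and those between treated libraries climb by at most 0.16.

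At 2 h with Fanchinoline, targets of ATF4, the transcription factor of the integrated stress response, stood above vehicle. The ATF4 list had a median log2 ratio of 0.35 over 33 measured genes, at percentile 100 of the random lists, with 5 members called higher and 0 lower. These were the transporters Slc1a4 (1.78, interval 1.65 to 1.92; 60.4 against 17.5 CPM), Slc6a9 (1.26) and Slc7a5 (1.22), the pseudokinase Trib3 (1.57) and Chac1 (1.02), a glutathione-degrading enzyme. Slc7a1, a cationic amino acid transporter, was also higher, with 1.65 (1.59 to 1.71; 268 against 85.4 CPM). Mitochondrially encoded genes were lower, with a median of -0.93 over 13 genes and 5 called. Length-adjusted, their median was -0.18 and 0 were called. Among random lists matched on length as well, they were at percentiles 0.00, 0.00, 0.06 and 2.66 at 2, 6, 12 and 24 h. They thus stayed low at 2, 6 and 12 h with length matched.

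In all, 118 of 8846 genes were called at 2 h, 80 higher and 38 lower. Among the highest with an ordinary symbol and at least 10 CPM were the kinase-related Peak1 (2.52, 2.30 to 2.77), Plekhm3 (2.58, 2.46 to 2.71; chromosome 1, 64785983 to 64956824), the Polycomb gene Phc3 (2.47), Pdpr (2.31), a subunit of pyruvate dehydrogenase phosphatase, Heg1 (2.23), the copper transporter Atp7a (2.02), the nuclear receptor Nr2c2 (1.83), Hipk2 (1.69) and Derpc (1.68). The toll-like receptor Tlr9 was at 1.14, as the only called member of 13 pattern recognition genes, and did not pass when length-adjusted (0.98). Fatty acid synthesis genes had a median of 0.41 over 10 genes at percentile 99.88, with Fasn, the fatty acid synthase, called (1.01); length-adjusted, the median was 0.32 and 0 members passed (Fasn 0.41), and among lists matched on length the percentile was 97.53. Among the lower genes were Rffl (-2.12), Rbis (-1.30), Hdgfl3 (-1.18) and the mitochondrial mt-Nd6 (-1.49), mt-Ts1 (-1.29) and mt-Nd4 (-1.23). Interferon-stimulated genes (22, median -0.22, percentile 0.32; -0.10 length-adjusted) and mitotic genes (27, median -0.23, percentile 0.02) lay low, each with 0 called.

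Of the 38 lower genes at 2 h, 21 share exon positions with another gene on the same strand (55.3%, against 9.4% of all compared genes), so their reads could be divided in more than 1 way. The share was 21.2% of the higher genes at 2 h (17 of 80), and 26.6% of the lower (29 of 109) and 11.5% of the higher genes (29 of 253) at 24 h. The entries of Nnt, nicotinamide nucleotide transhydrogenase, moved against each other: ENSMUSG00000025453 was at 97.0 against 15.7 CPM and ENSMUSG00000116207 at 7.56 against 85.6 CPM, while their sum was 105 against 101 CPM. Atrip (-1.28), Maskbp3 (-1.25), Pagr1a (-1.25), Dpm1 (-1.86) and 1 entry of Zc3h11a (-1.96) overlap other genes in the same way. With length adjustment 61 genes were called, 41 higher and 20 lower, and 48 of the 118 genes called at 2 h were still called. Among others mt-Nd6 (-0.51), mt-Nd4 (-0.52), mt-Ts1 (-0.10) and Rbis (-0.63) no longer passed, and the mitochondrial median became -0.18.

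By 6 h, hypoxia-inducible and glycolytic genes stood well above vehicle, together with cholesterol and fatty acid synthesis genes. The hypoxia list had a median of 0.97 over 12 genes (percentile 100), with 6 called higher and 0 lower: the collagen hydroxylase subunit P4ha2 (2.59), the mitophagy receptor Bnip3 (1.88, 1.74 to 2.03; 54.8 against 14.9 CPM), the glucose transporter Slc2a1 (1.78), Ankrd37 (1.70), pyruvate dehydrogenase kinase Pdk1 (1.48) and the oxygen sensor Egln1 (1.17). Glycolysis genes had a median of 0.76 over 17 genes (percentile 100), with 4 called higher, among them the lactate exporter Slc16a3 (2.31, 2.25 to 2.36; 477 against 96.2 CPM) and Pfkl (1.65), a phosphofructokinase. Slc2a1 belongs to both lists.

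Cholesterol synthesis and uptake genes had a median of 0.67 over 24 genes at 6 h (percentile 100). Of these, 5 were called higher and 0 lower, among them Lss (1.21), the sterol carrier Stard4 (1.06) and Acat2 (1.05). Length-adjusted, 2 cholesterol genes passed, and Lss (0.85) and Stard4 (0.96) did not. Fatty acid synthesis genes had a median of 0.60 (0.48 length-adjusted), with Fasn (1.40), Scd2 (1.27) and Acaca (1.12) called, of which 0 passed when length-adjusted (0.74, 0.996 and 0.65). The transferrin receptor Tfrc was higher (1.36). The ATF4 list was still above its random lists (median 0.24, percentile 99.48), with only Ddit4 called (1.32).

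At 6 h 172 genes were called, 139 higher and 33 lower. Beyond the genes above, high genes with an ordinary symbol and at least 10 CPM at 6 h were Peak1 (2.89), Phc3 (2.60), Mfsd4a (2.59), Plekhm3 (2.57), Pdpr (2.45), Derpc (2.33), Atp7a (2.29), Heg1 (2.16) and Bcar1 (1.92), a focal adhesion adaptor. Lower genes included Rffl (-2.49), the apolipoprotein L gene Apol7c (-1.47), Hdgfl3 (-1.36), the nuclear non-coding RNA Malat1 (-1.28), and the overlapping Zc3h11a (-2.55), Dpm1 (-2.38), Commd1b (-1.67) and Maskbp3 (-1.33). Mitochondrial mt-Nd6 (-1.60), mt-Ts1 (-1.27) and mt-Atp6 (-1.19) were called, and length-adjusted (-0.61, -0.12 and -0.32) these 3 did not pass. The list of mitochondrial messages, which holds no transfer RNA such as mt-Ts1, had a median of -0.85 with 5 called, of which 0 passed when length-adjusted. With length adjustment 88 genes were called, 64 higher and 24 lower, and 66 of the 172 were still called. The hypoxia, glycolysis and cholesterol medians were then 0.91, 0.77 and 0.76, and the mitochondrial median -0.11.

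After 12 h the hypoxia, glycolysis and sterol genes stood far above vehicle, and the ATF4 list had moved below vehicle. Hypoxia genes had a median of 1.29 with 8 of 12 called higher, led by P4ha2 (3.45, 3.04 to 4.02; 13.5 against 1.19 CPM). Glycolysis genes had a median of 1.11 (length-adjusted 1.12, against 1.15 at 24 h) with 10 of 17 called higher, including Slc16a3 (2.62), Pfkl (2.00), phosphoglycerate kinase Pgk1 (1.65) and Slc2a1 (2.04). Cholesterol genes had a median of 1.03 with 12 of 24 called higher, among them Lss (1.64), Acat2 (1.56) and Stard4 (1.38). The ATF4 list had a median of -0.39 (percentile 0.00), with Nupr1 (-1.76) and Slc1a4 (-1.04) called lower and Ddit4 higher (1.43).

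In total 272 genes were called at 12 h, 206 higher and 66 lower. Among genes with an ordinary symbol, the nucleotide kinase Ak4 was the highest at 4.95 (4.35 to 5.99; 14.7 against 0.427 CPM), followed among genes not yet given by Mgarp (3.32), a mitochondrial protein, with Peak1 (2.93), Bcar1 (2.78), Plekhm3 (2.71), Mfsd4a (2.49), Pdpr (2.45), Bnip3 (2.40) and Atp7a (2.39). Lower genes included Rffl (-2.10), Apol7c (-1.65), Erdr1 (-1.58), Malat1 (-1.56), Ppp1r14a (-1.49), the histone gene H2bc4 (-1.36), and the overlapping Dpm1 (-2.92), Zc3h11a (-2.34) and Maskbp3 (-1.51). Ribosome biogenesis genes lay low (24 genes, median -0.41, percentile 0.00, 0 called). With length adjustment 177 genes were called, 125 higher and 52 lower, and 123 of the 272 were still called. H2bc4 (-0.97) no longer passed, and 7 hypoxia, 11 glycolysis and 11 cholesterol genes were then called higher.

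After 24 h with Fanchinoline, hypoxia and glycolysis genes stayed high, sterol genes were less far above vehicle, and ATF4 targets were at their lowest. Ak4 stood at 5.26 (4.66 to 6.30; 18.2 against 0.427 CPM; chromosome 4, 101419277 to 101466995), Mgarp at 3.70 (3.29 to 4.26; 16.0 against 1.19 CPM; chromosome 3, 51388412 to 51396738) and P4ha2 at 3.19 (2.77 to 3.75). The hypoxia median was 1.26 with 8 of 12 called higher, among them Bnip3 (2.27), Slc2a1 (1.86) and Pdk1 (1.85). Glycolysis genes had a median of 0.96 with 8 of 17 called higher, including Slc16a3 (2.34), Aldoc (1.87) and Pfkl (1.78); Pgk1 was at 1.67 and its pseudogene copy Pgk1-rs7, which shares sequence with it, at 2.55 (20.5 against 3.48 CPM).

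**Figure D2:**
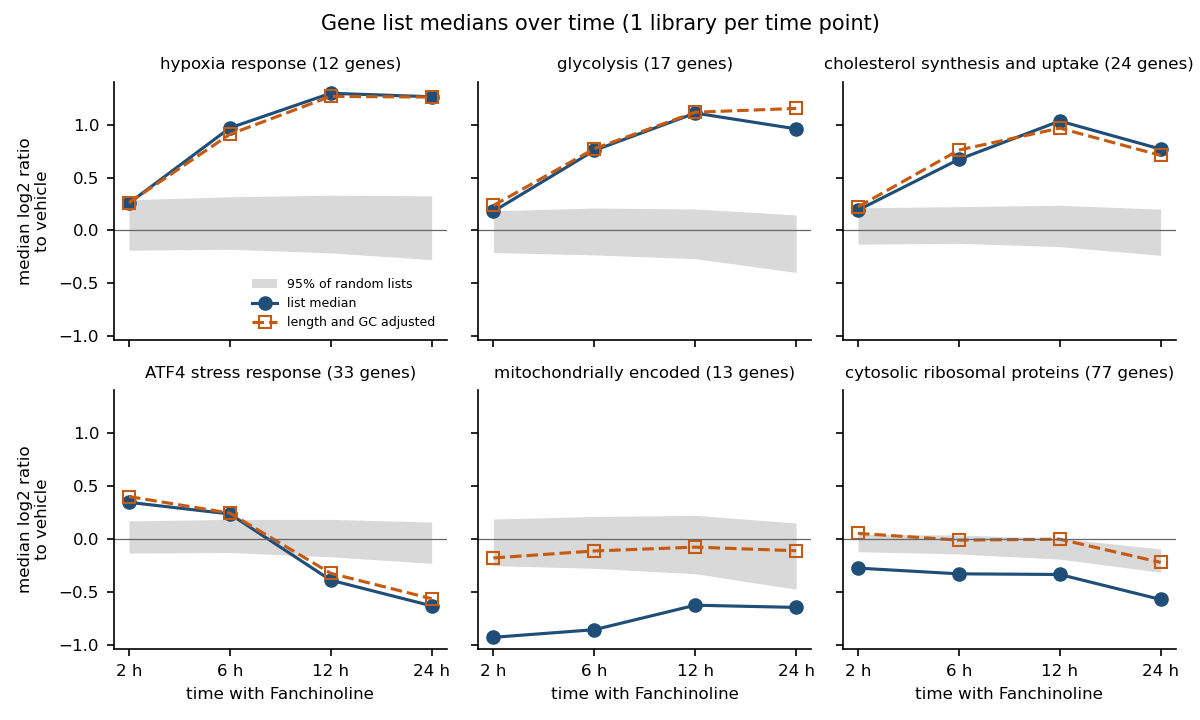
Median log2 ratio to vehicle (y axis) of 6 gene lists at 2, 6, 12 and 24 h (x axis), with 1 library per time point. Circles are medians, open squares the medians of length-adjusted ratios, and grey bands hold 95% of 10000 random lists matched on expression. Hypoxia, glycolysis and cholesterol genes climb to medians of 1.29, 1.11 and 1.03 at 12 h, the ATF4 list passes from 0.35 to -0.63, and the adjustment brings the mitochondrial list from -0.64 to -0.11 at 24 h.

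The ATF4 list had a median of -0.63 over 33 genes at 24 h (percentile 0.00), with 8 called lower and 1 higher. Nupr1, a stress-induced chromatin protein, was at -2.47 (-2.85 to -2.16; 2.08 against 11.8 CPM), the cystathionine lyase Cth at -1.60, asparagine synthetase Asns at -1.40 and Slc1a4 at -1.38, while Ddit4, an inhibitor of mTORC1 that is also induced in hypoxia, was at 1.23. Ddit3, which encodes CHOP, was at -0.55 and did not pass. Endoplasmic reticulum chaperone and unfolded protein response genes had a median of -0.31 over 24 genes (percentile 1.24; -0.15 length-adjusted) with 0 called; Manf was at -0.95 and Hspa5 at -0.45. Heat shock genes had a median of -0.42 over 11 genes (percentile 0.94), with Hspe1 at -0.96 and Hspa8 at -0.87 and 0 called.

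Sterol and fatty acid genes were above vehicle at 24 h with medians of 0.77 (24 genes) and 0.66 (10 genes), at percentiles 100 and 99.99. Lss (1.42), Stard4 (1.21) and Acat2 (1.12) were called among the first, and Scd2 (1.34), Acaca (1.03) and Fasn (1.03) among the second. Length-adjusted, Stard4 (0.99), Acaca (0.50) and Fasn (0.49) did not pass, and 5 cholesterol and 1 fatty acid genes did. Acat2 has a near copy, so its reads are uncertain. Lysosome genes had a median of 0.26 over 34 genes (percentile 99.96) with 0 called, the largest being Atp6v1a (0.90), a proton pump subunit, and the cholesterol exporter Npc1 (0.80). Among TFEB and mTORC1 feedback genes Fnip1 (1.71) and Flcn (1.69), which act on lysosomal nutrient sensing, were called, within a median of 0.23 over 9 genes (percentile 89.19; 0.09 length-adjusted). In iron handling, Tfrc was called at 1.49 and the ferritin heavy chain Fth1 was at -0.94. Autophagy genes had a median of 0.23 over 27 genes (percentile 97.49; 0.15 length-adjusted), where only the mitophagy receptors Bnip3 and Bnip3l (1.78) were called; Sqstm1 was at -0.28.

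Genes of protein synthesis were below vehicle at 24 h. Cytosolic ribosomal proteins had a median of -0.57 over 77 genes (percentile 0.00), with Rps24 (-1.09), Rpl35 (-1.07) and Rps26 (-1.05) called lower, and ribosome biogenesis genes a median of -0.48 over 24 genes (percentile 0.00), with Ppan called (-1.09), Nop56 at -0.96 and Myc at -0.69. Ribosomal protein transcripts are short, and with length adjustment their median was -0.22, against -0.36 for ribosome biogenesis, and Rpl35 (-0.68) and Rps26 (-0.64) did not pass. Nuclear oxidative phosphorylation genes (35 genes, median -0.28) and proteasome genes (31 genes, median -0.35) had 0 called, and their length-adjusted medians were 0.03 and -0.14.

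Of 20 apoptosis regulators 2 and of 12 p53 targets 1 were called at 24 h. Both medians lay within 95% of the random lists matched on expression, and at percentiles 98.16 and 98.37 of lists matched on length as well. Bcl2l11, which encodes the pro-apoptotic BIM, was at 2.13 and Apaf1, of the apoptosome, at 1.08, as the 2 called members among 20 apoptosis regulators (median 0.21, percentile 94.30; 0.35 length-adjusted, where Apaf1, at 0.70, did not pass). Trp53inp1 (1.53) was called among 12 p53 targets (median 0.31, percentile 96.39), where Cdkn1a, the cell cycle inhibitor p21, was at 0.96 (45.5 against 23.4 CPM) and passed only when length-adjusted (1.14). DNA replication genes had a median of 0.31 over 30 genes (percentile 99.97), with Pola1 called (1.02; 0.79 length-adjusted, not passing). Mitotic genes were near vehicle (27 genes, median 0.09, percentile 83.21; 0.03 length-adjusted), with the checkpoint kinase Bub1 called higher and Mki67 at 0.59.

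Of class II, class I and maturation genes of dendritic cells 0 were called at 24 h. Class II antigen presentation genes had a median of -0.40 over 13 genes (percentile 3.34) with 0 called, where the invariant chain Cd74 was at -0.81 and H2-Ab1 at -0.78 (1090 against 1870 CPM); the length-adjusted median was -0.14. The class II list was lower against its random lists at 6 h (median -0.27, percentile 1.5; -0.02 length-adjusted) and 12 h (-0.39, percentile 0.25; -0.13 length-adjusted), and at percentiles 8.86, 1.68 and 16.77 at 6, 12 and 24 h among lists matched on length as well. The cDC1 identity list lay low at 6 h (median -0.24, percentile 0.31; -0.08 length-adjusted) and 12 h (-0.31, percentile 0.11), and at percentiles 0.01, 0.00 and 0.82 at 6, 12 and 24 h among lists matched on length. At 24 h, among these 22 genes (median -0.26, percentile 4.77) only Cd8a was called (-1.24), while the chemokine receptor Xcr1 was at -0.13, the lineage factor Irf8 at -0.38 and Batf3 at -0.72. Class I genes had a median of -0.26 over 17 genes (-0.13 length-adjusted) with 0 called and H2-K1 at -0.34, and maturation genes a median of 0.03 over 13 genes (0.19 length-adjusted) with 0 called and the costimulatory Cd86 at -0.33. Interferon-stimulated genes had a median of 0.26 over 22 genes (percentile 97.42), with Ifit2 (1.48) and Parp14 (1.06; 0.65 length-adjusted, not passing) called and Isg15 at 0.03. Of 13 NF-kB and cytokine genes (list median -0.20) Rel was called at 1.17 and did not pass when length-adjusted (0.77). Tnf was at 2.74 against 2.84 CPM, below the minimum for calls. Tlr9 was at 1.46.

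In all, 362 genes were called at 24 h, 253 higher and 109 lower; with length adjustment 244 were called, 161 higher and 83 lower, and 170 of the 362 were still called. Further high genes were Peak1 (3.09), Plekhm3 (2.91), Derpc (2.90), which overlaps Chtf8, Bcar1 (2.89), Atp7a (2.65), Pdpr (2.56) and the receptor kinase Axl (2.37). For 24 h over 2 h, Bcar1 was at 2.54, Axl at 1.46 and Derpc at 1.22. Atp7a (0.63), Peak1 (0.58), Plekhm3 (0.33) and Pdpr (0.26) differed less between these treated libraries. Most of the ratio of these latter genes lies between the 1 vehicle library and 2 h. Further low genes were Rffl (-2.63), Apol7c (-2.52, -2.76 to -2.31; 4.66 against 26.9 CPM), Erdr1 (-2.16), Malat1 (-1.75), the mitochondrial ribosomal RNA mt-Rnr1 (-1.71), and the overlapping Zc3h11a (-4.08), Dpm1 (-3.20) and Commd1b (-1.65). The other entry of Zc3h11a was at -0.92, and the sum of both was 17.1 against 50.7 CPM. Scaling by total count alone gave 362 higher and 75 lower genes and moved the median of all genes to 0.10; without the vehicle library, 24 h over 2 h gave 137 genes, 76 higher and 61 lower.

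**Figure D3:**
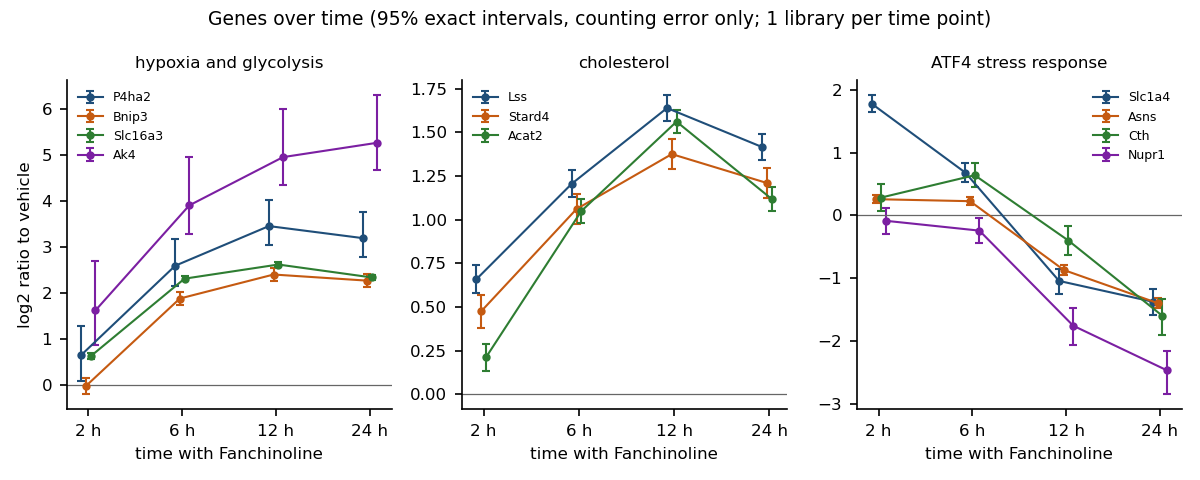
Log2 ratio to vehicle (y axis) of 11 genes at 2, 6, 12 and 24 h (x axis), with 95% exact intervals for counting error only and 1 library per time point. Ak4 reaches 5.26 at 24 h, Lss 1.64 at 12 h, and Slc1a4 passes from 1.78 at 2 h to -1.38 at 24 h.

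Across time points, 44 genes were called higher and 15 lower at all 4 times against the 1 vehicle library. Simulated unchanged libraries, with the vehicle library simulated as well, gave 0 such genes in 50 runs. Independent lists of these sizes would share 0.000837 higher and 1.3e-05 lower genes. Neither expectation allows for a departure of the real vehicle library, such as its balance of long and short transcripts, which all 4 ratios share. Part or all of the overlap may therefore rest on the shared vehicle library, which could not be divided. With length adjustment 27 higher and 12 lower genes were called at all 4 times.

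Between consecutive treated libraries, where vehicle plays no part, the hypoxia and glycolysis genes stood higher at 6 h than at 2 h, and the ATF4 genes lower at 12 h than at 6 h. For 6 h over 2 h 29 genes were called, 20 higher and 9 lower, with Ak4 (2.28, 1.90 to 2.77), Mgarp (2.06), P4ha2 (1.94), Bnip3 (1.90), Slc16a3 (1.68), Bcar1 (1.56), Pdk1 (1.13) and Pfkl (1.11) among the higher and Slc1a4 (-1.10) and Chac1 (-1.12) among the lower. The medians of the hypoxia, glycolysis and cholesterol lists were 0.73, 0.49 and 0.48, each at percentile 100. For 12 h over 6 h 27 genes were called, 5 higher and 22 lower. Of the ATF4 list 8 of 33 members were lower (median -0.59, percentile 0.00), including Slc1a4 (-1.72), Nupr1 (-1.51), Asns (-1.10) and Cth (-1.04), and Mgarp (1.30) and Ak4 (1.05) were again higher.

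For 24 h over 12 h 13 genes were called, 8 higher and 5 lower, and 0 with a minimum of 30 CPM. The receptor kinase Axl (1.49, 1.28 to 1.73) was higher, and Cth (-1.20) and the overlapping Zc3h11a (-1.74) were lower. Cholesterol genes had a median of -0.26 and ribosomal protein genes of -0.23, both at percentile 0.00, and interferon-stimulated genes one of 0.35 at percentile 100, with Oas1a called (1.15). Mfsd4a, whose exons face Elk4 on the other strand, moved by 4.18 at 6 h over 2 h and by -3.92 at 24 h over 12 h. Libraries without strand do not separate the reads of such pairs. Of the 44 gene entries named as highest or lowest against vehicle, 13 overlap a gene on the other strand, with Peak1, Pdpr, Heg1, Rffl and Bnip3 among them.

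Over the 5 libraries, 11 of 17 glycolysis, 9 of 14 hypoxia and 13 of 24 cholesterol genes rose and 24 of 77 ribosomal protein genes fell along log2(hours + 1), although the cholesterol median was lower at 24 h than at 12 h. Of 13877 genes tested with edgeR's quasi-likelihood test, 716 rose and 537 fell at an adjusted p under 0.05, with 1 library per time point. Rising genes had a median transcript length of 5450.5 and falling genes of 1997, as ratios to vehicle also differed by length; ribosomal protein transcripts are short. Adjusted over each list alone, 14 glycolysis, 11 hypoxia and 20 cholesterol genes rose, with 0 falling in each, and 54 ribosomal protein genes fell. Other falling members were 8 of 24 ribosome biogenesis genes (16 adjusted over the list alone) and 5 of 13 class II genes (7 adjusted over the list alone, where 2 rose). Slopes are named among genes past the threshold with a mean of at least 10 CPM and an ordinary symbol, which leaves out Ak4, Mgarp and P4ha2. The steepest rises per doubling of hours + 1 were those of Bcar1 (0.725 ± 0.0851 SE, edgeR adjusted p = 0.0177), Slc16a3 (0.615), Bnip3 (0.606), Pgk1-rs7 (0.576), Derpc (0.560) and Atp7a (0.480). The rise of Atp7a lies mostly between vehicle and 2 h (2.02), with 0.63 for 24 h over 2 h. Apol7c (-0.504 ± 0.0433 SE, edgeR adjusted p = 0.0127), Malat1 (-0.376), mt-Rnr1 (-0.335), Maskbp3 (-0.322) and Apol10b (-0.301) were among the steepest falls within the same limit, which leaves out Dpm1, Rffl and Nupr1. The count rests on single time points: edgeR called 0 genes without 12 h (2815 at an unadjusted p under 0.05; 901 with DESeq2), 41 without 24 h, 339 without 6 h, 2064 without 2 h and 2158 without vehicle. It was also 0 with edgeR on a scale of plain hours (2730 unadjusted; 937 with DESeq2) and with no filter (4843 unadjusted; 2342 with DESeq2), while DESeq2's Wald test with the same settings called 2451.

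Markers of other cell types were mostly below 10 CPM in all 5 libraries. This held for every listed marker of T and NK cells, of neutrophils and mast cells, of fibroblasts, endothelium and epithelium, and of erythroid cells. The endothelial Cdh5 and the epithelial Epcam came close to that minimum, each with 9.91 CPM at 24 h. Of macrophage markers, 7 were measured, with a median of -0.80 at 24 h (percentile 0.00; -0.48 length-adjusted): C1qa was called (-1.09; -0.69 length-adjusted, not passing), C1qc was at -0.98 and Lyz2 at -0.85, while Csf1r was at 0.93. Among cDC2 markers Itgam was at 0.75 and Ccr2 at 0.50, and among plasmacytoid markers Tcf4 at 0.37 and Bst2 at 0.03, with 0 called. The immunoglobulin gene Ighm was the single measured B cell marker, at 92.3 CPM after 24 h against 31.5 CPM in vehicle (1.55). A mixed list of non-coding and histone RNAs, written for signs of RNA quality, had a median of -0.51 at 2 h and -0.81 at 24 h over 7 genes. Its percentiles were 0.02 and 0.00, and its length-adjusted medians -0.19 and -0.59. In this list Gas5 was at -0.95 and H2bc4 at -0.97 at 24 h. Whether such falls reflect RNA quality was not tested.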

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

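All tests in this part were chosen after the results were seen. Several genes were called in opposite directions at 2 h and at 24 h against the same vehicle library, which drew attention to them; with 1 library per time point the difference between times was not tested. Slc1a4 stood at 1.78 at 2 h and -1.38 at 24 h, Trib3 at 1.57 and -1.14, Slc6a9 at 1.26 and -1.01, and Chac1 at 1.02 and -1.18. These 4 belong to the ATF4 list, whose median passed from 0.35 (percentile 100) to -0.63 (percentile 0.00). Pde2a went from 1.08 to -4.10 and shares exon positions with another gene, and Cers4 went the other way, from -1.06 to 1.20; length-adjusted, Pde2a at 2 h (0.84) and Cers4 at 24 h (0.67) did not pass.

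The ATF4 pattern was set against technical sources. Transcript length and GC content do not account for it, since the length-adjusted medians were 0.40 at 2 h and -0.56 at 24 h, against 0.35 and -0.63 unadjusted, although Trib3 (-0.93) and Chac1 (-0.91) no longer passed at 24 h. The median of 24 h over 2 h, without vehicle, was -0.89 (-0.82 length-adjusted) and lay below the random lists. The fall between these times thus does not need the vehicle library. The value for 24 h over 2 h is the difference of the 2 ratios that drew attention, so it is no separate test. The place of the list above vehicle at 2 h and below it at 24 h rests on the 1 vehicle library. A change of medium at the start of treatment and the use of nutrients over 24 h remain open beside an effect of Fanchinoline: with 0 vehicle libraries at 2 to 24 h, medium change or hours in culture and the compound cannot be told apart.

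The rise of hypoxia and glycolysis genes was treated in the same way. With length adjustment their medians at 24 h were 1.26 and 1.15, so a bias of transcript length or GC content does not account for them. Without vehicle, the medians of 24 h over 2 h were 0.89 and 0.85 (length-adjusted 0.91 and 0.91), above the random lists. This argues against the vehicle library as the whole source. Hours in culture stay open, as cells growing denser may also lower oxygen, and with 0 vehicle libraries at 2 to 24 h this cannot be told apart from the compound.

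The rise of ratios with transcript length was seen against vehicle at all 4 times. Sequencing depth does not account for it at 2 h. The depth ratio of 2 h over vehicle was 1.12, and 2 pairs of treated libraries had ratios of 1.13 and 1.14. These pairs differed between long and short quintiles by at most 0.059, against 0.574 for 2 h over vehicle. No treated pair had a depth ratio as large as 6 h or 24 h over vehicle, so depth was not tested for those. GC content does not account for the rise at 24 h, as within each quintile of GC content the difference was at least 0.70. For 24 h over 2 h it was 0.16, so most of the difference lies between vehicle and the 2 h library. The RNA or the library preparation of the vehicle sample and a response of the cells within 2 h cannot be told apart, because the vehicle group holds 1 library.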

How the results depend on the processing

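The alternatives with length adjustment, without overlapping genes and without vehicle were chosen after the data were seen. With 1 library per time point, the replicate-based tests planned for a replicated table were not run. No paired analysis was possible because the table holds 1 library per time point. DESeq2 size factors, total counts and a prior count of 0.5 kept every count of called genes, and the trend count where run, within 1.5 times, and all 96 named values stayed past the rule; length adjustment left 88 of 96 past it. At 2, 6, 12 and 24 h the counts were 398, 493, 651 and 848 with a minimum of 1 CPM, 75, 113, 175 and 223 with 30 CPM, 957, 1200, 1429 and 1864 at 1.5-fold, and 14, 21, 29 and 33 at 4-fold. Length adjustment gave 61, 88, 177 and 244 at these times, of which 48, 66, 123 and 170 were called the same way without it. The comparison of 24 h over 2 h gave 137 in place of 362, of which 85 were called the same way at 24 h over vehicle. Between consecutive times (29, 27 and 13 genes) the counts were 132, 133 and 133 with 1 CPM, 12, 17 and 0 with 30 CPM, 105, 114 and 72 at 1.5-fold, 7, 1 and 4 at 4-fold, and 7 for 24 h over 12 h without overlapping genes. More or fewer genes enter under another minimum or fold; for the other settings the cause was not tested.

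The trend count (1253) was 0 with no filter (edgeR, 4843 unadjusted; 2342 with DESeq2), 0 on plain hours (2730 unadjusted; 937 with DESeq2), 776 on ranks of time, 2158 over treated libraries alone (773 shared) and 2451 with DESeq2's Wald test (1226 shared; 2153 adjusted p not given). Leaving out each time point gave 0 (12 h; 2815 unadjusted, 901 with DESeq2) to 2158 (vehicle), with 41 without 24 h, 339 without 6 h and 2064 without 2 h. Of list medians, hypoxia moved to 0.76 at 6 h with a minimum of 1 or 30 CPM, and to 1.07 and 1.09 at 12 h; the ATF4 list at 24 h was -0.53 by total count and -0.51 with 30 CPM; glycolysis at 24 h was 1.15 length-adjusted. Without vehicle, 24 h over 2 h gave 0.47 for cholesterol, -0.89 for ATF4 and 0.89 for hypoxia. Length adjustment reversed the nuclear oxidative phosphorylation list (0.155, 0.117, 0.087 and 0.03 at the 4 times), ribosomal proteins at 2 h (0.055) and to 0.00 at 12 h, and the proteasome at 2, 6 and 12 h (0.019, 0.026 and 0.025). Mitochondrially encoded genes were at 0.23 for 24 h over 2 h. The cause was not tested beyond the adjustment itself. At 10 CPM the depth gives 328 to 427 counts; the spread between cultures was not measured.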

Other observations

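The test in this part was planned before its result was seen. Heat shock genes, macrophage markers and the mixed list of non-coding and histone RNAs fell over the time course in part. Apoptosis regulators and interferon-stimulated genes rose in part. Heat shock genes fell in 3 of 14 (6 adjusted over the list alone), non-coding and histone RNAs in 5 of 12 (7 adjusted over the list alone) and macrophage markers in 4 of 9 (4 adjusted over the list alone, where 1 rose), with 0 rising over all genes. Apoptosis regulators rose in 6 of 22 (6 adjusted over the list alone, where 1 fell) and interferon-stimulated genes in 4 of 35 (5 adjusted over the list alone), with 0 falling over all genes. For comparison, 716 of all 13877 tested genes rose and 537 fell, and the trend was not length-adjusted. The interferon list median was -0.22, -0.16 and -0.15 at 2, 6 and 12 h, and it was above vehicle only at 24 h (0.26). In the ATF4 list 1 of 35 rose and 1 fell (0 adjusted over the list alone).

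Other lists had medians near vehicle at 24 h. LXR targets (5 genes) were at 0.11, with Srebf1 at 0.76 and Arl4c at -0.52; NRF2 targets (20 genes) were at -0.16 (0.01 length-adjusted), with Gclm at -0.71 and Hmox1 at 0.04; and calcium handling genes (25 genes) were at 0.15 (0.08 length-adjusted), with Itpr3 called at 1.17 and Itpr1 at 0.90 (length-adjusted, Itpr3 was at 0.68 and did not pass, and Ryr1 was called lower at -1.07). Pattern recognition genes were at 0.06 over 13 genes (0.02 length-adjusted). Immediate early genes were at -0.06 over 14 genes, with Jund called at -1.12 and Junb at -0.78 (length-adjusted, Jund was at -0.72 and did not pass, and Fos just passed as higher), and housekeeping genes at -0.06 over 15 genes (0.03 length-adjusted); scaling by total count turned both medians to 0.04 and 0.05. Among the housekeeping genes, Pgk1 was called at 1.67, Gapdh was at 0.88 and Actb at -0.85, all at 24 h.

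The number of genes following the time course was set against other orders of the 5 libraries. Of 100 orders, the real one included, 1 gave as many genes as the real order (1253), and the highest of the other orders gave 2. At this setting the count was thus particular to the real order among those drawn. The real order itself gave 0 genes on plain hours and 0 without 12 h. A count near 0 for another order is therefore weak evidence, and an arbitrary order was not excluded. The comparison of orders also does not separate the compound from hours in culture, which share the order.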
